A study of Mus musculus with 16 samples.

How the data were processed

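Carotid arteries of 16 female ApoE-/- mice were each measured on 1 Agilent mouse miRNA array (Sanger release 12 design, 1 colour, Cy3): 3 uninjured, 3 at day 1, 3 at day 7, 3 at day 14 and 4 at day 28 after wire injury. Per the labels, total RNA was isolated with a miRNeasy kit and labelled with Cy3-pCp. The deposited scanner files hold 13715 features each, with the intensity of every spot after the authors' background handling in Agilent Feature Extraction. The deposited value table holds 610 of the 611 mouse miRNAs on a linear intensity scale, and 99.9% of its values lie within 0.1% of the total gene signal in the scanner files. The column medians of that table were 13.0, 13.5 and 8.44 (day 1), 16.6, 11.5 and 11.0 (day 7), 7.67, 11.2 and 14.2 (day 14), 9.00, 16.1, 11.6 and 7.62 (day 28), and 3.81, 5.36 and 7.93 (uninjured), so its columns were not brought to a common centre. How the spot background was estimated upstream and how the animals were assigned to groups are not given in the sources used here. Only 1 spot was saturated, a viral probe marked as an outlier.

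The processed signal was averaged on the linear scale over the spots of a probe without an outlier mark, from 13000 spots of mouse and viral probes per array. Each array was divided by the 75th percentile of the 395 mouse probes that were well above background on all 16 arrays. Values under a floor of 0.0181, the median over arrays of the lowest scaled signal well above background, were set to it, and log2 was taken (floor log2 -5.79). A probe counted as well above background on an array when at least 50% of its unmarked spots were. The brightest probe stood for each miRNA. Tested were the 321 miRNAs well above background on every array of at least 1 group, of which 219 were so on all arrays. Percentages of probes well above background and the 75th percentiles given in the report describe the depth.

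Groups were compared with limma 3.58.1 in R 4.3.3 (files read with the package data.table, version 1.17.8): 1 linear model over the 5 groups, with no covariate, moderated tests (estimated prior degrees of freedom 1.98) and Benjamini-Hochberg adjustment within each comparison, called at an adjusted p under 0.05. The comparisons were each day against uninjured, successive days with each other as the test of whether the effect of injury differed between days, and a moderated F test over the 4 days. With 3 arrays against 3 an exact permutation test of a single value cannot give a two-sided p below 0.1, so only the tests that pool the spread over miRNAs were used. Each fit was repeated with slide as a block and, where 2 groups share a slide, within that slide. In the fit with all slides 0 miRNAs had a slide effect by limma after adjustment, 39 at an unadjusted p under 0.05, and the median absolute slide effect was log2 0.23.

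In total 20 lists of miRNAs, written from general knowledge before the data were examined, were tested with camera against the other tested miRNAs (preset correlation 0.01 and, as an alternative, an estimated correlation), adjusted over the lists of a comparison with at least 3 tested members. They are injury-associated, smooth muscle contractile-associated, leukocyte-enriched, endothelial, erythroid, striated muscle, epithelial miR-200 family, neuronal, liver, hypoxia-associated, miR-17-92 cluster and paralogs, let-7 family, Dlk1-Dio3 cluster, miR-29, miR-30 and miR-15/16 families, miR-23/27/24 clusters, miR-199 and miR-214 mesenchymal, and miR-34 and miR-181 families. Counts adjusted over the list alone use only the members' p-values. miRNAs were named by a rule: per direction the 10 largest called differences against uninjured, or 5 between days, with the arrays of the groups wholly apart, and up to 4 members of each list with the smallest p. A fold is given as "at least" where a miRNA was well above background on every array of only 1 of the groups, or on 0 arrays of 1 group, or where an array of the lower group lay at the floor. It then takes arrays without detection at their lowest detected signal if that is higher, and the log2 difference beside it is the fitted one.

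The comparisons, the lists, the naming rule and all alternatives but 1 were chosen before the data were examined. Alternatives tried were: scaling to the 75th percentile over all mouse probes, to the median, by quantiles or not at all; normexp background with offset 50; no filter, or only miRNAs detected on all arrays; a floor 2 times or 0.5 times as high; outlier spots kept; mean over probes; total gene signal; the authors' value table; slide as a fixed or random block; within 1 slide; replicate number as a block, alone and with slide; only the 2 groups compared; array weights; trend and robust moderation; a log2 difference of at least 1 as well; and each array left out in turn. Leaving out both arrays that stand apart was added after the data had been seen. The pipeline was tested on simulated data with 321 miRNAs, 60 of them changed, in 20 runs. At the 4 days 63.3 to 67.2% of changes of log2 1 and 87.7 to 89.5% of changes of log2 2 were recovered. Of the calls 3.72 to 4.9% were false. camera called the shifted list in 20 of 20 runs and 0 of 320 unchanged lists. The simulated miRNAs varied independently of each other, whereas the correlations estimated within the lists in the data were 0.23 to 0.95. The simulation therefore does not show how often lists with correlated members are called falsely. Where a called miRNA had more than 1 detected probe, the other probes disagreed in sign for 2 of 57 at day 1 (let-7i and miR-125a-5p), 1 of 75 at day 7 (miR-497), 0 of 64 at day 14 and 0 of 44 at day 28. The RefSeq table for GRCm38.p6 was used only for names and for which miRNA genes neighbour each other.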

Results

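MicroRNA (miRNA) levels were measured in 16 carotid arteries of female ApoE-/- mice kept on a western-type diet. These mice lack apolipoprotein E and are prone to atherosclerosis. In 13 of the arteries a wire had been used to injure the vessel, and RNA was taken at day 1 (n = 3), day 7 (n = 3), day 14 (n = 3) or day 28 (n = 4) after the injury. Another 3 arteries were left uninjured as the control. The series is about the formation of a neointima, the inner layer of tissue that grows in an artery after such an injury. Total RNA of each artery was labelled with Cy3 and hybridized to 1 Agilent mouse miRNA array with probes for 611 mouse miRNAs. Of the 1759 mouse probes, 33.5% were well above background on an average array, and 321 miRNAs were tested. The 75th percentile of the signal over the 395 probes detected on all arrays ran from 401 to 624.1 intensity units in the uninjured group, 483.8 to 761.3 at day 1, 816.2 to 1214 at day 7, 518.5 to 1432 at day 14 and 566.5 to 1097 at day 28. Between 251 and 292 miRNAs were detected on the uninjured arrays and between 285 and 335 on those of injured arteries. Across miRNAs, which are not independent replicates, arrays of 1 group correlated with r from 0.973 to 0.996 in the uninjured group and from 0.929 to 0.971 at day 14, the lowest of the 5 groups. The arrays lay on 2 slides: day 1, day 7 and replicates 1 and 2 of day 28 on slide 1, and the uninjured, day 14 and other day 28 arrays on slide 2. Day 1 and day 7 therefore differ from uninjured in slide as well as in injury, and only the 4 arrays of day 28 tie the slides together. For this reason counts, and called lists compared between the slides, are given with slide as a block as well. The same is done for named miRNAs, and for values within 1 slide, where stated. The block raised the median SE from 0.24 to 0.37 at day 1 and day 7 and from 0.23 to 0.26 at day 28, so that a call can end in it without a smaller difference. Every comparison used limma, and its p-values measure the spread between animals as far as the series design, with 3 to 4 animals per group, states. The number of arrays limits the precision.

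Day 1 against uninjured asks which miRNAs had changed soon after the injury. miR-223, abundant in neutrophils and monocytes, rose 17.2-fold (log2 4.10 ± 0.17 SE, n = 3 and 3, adjusted p = 1.46e-09), from a mean scaled log2 signal of 0.46 ± 0.13 (SD) to 4.57 ± 0.07 (SD). miR-142-3p and miR-142-5p, made in blood cells, rose 8.38-fold (log2 3.07 ± 0.37 SE) and 6.39-fold (log2 2.68 ± 0.37 SE). With slide as a block their differences were 1.89 (adjusted p = 0.0154) and 1.63 (adjusted p = 0.0513). On day 28 replicate 2 they stood at 1.52 and -0.57, against -0.30 to 0.26 and -2.35 to -1.79 on the other day 28 arrays. As the day 28 arrays set the block, these smaller differences may rest largely on that array. miR-21, known to rise in injured arteries, increased 4.99-fold (log2 2.32 ± 0.22 SE, adjusted p = 4.99e-06), and its other strand miR-21* rose at least 3.58-fold. miR-340-5p rose at least 4.99-fold (log2 2.74 ± 0.19 SE). miR-375, best known from endocrine cells, was at least 5.99-fold lower (log2 -2.81 ± 0.56 SE, adjusted p = 0.00197), and miR-199b* 2.95-fold lower (log2 -1.56 ± 0.15 SE). When slide was a block miR-223 differed by 4.19, miR-21 by 2.30, miR-340-5p by 2.41, miR-375 by -4.47 and miR-199b* by -1.22, all still past the threshold. The block rests on the 4 day 28 arrays, and miR-375 stood at -3.20 on replicate 2 of these and at -5.79 to -5.03 on the others, so its block values rest largely on 1 array. miR-100, miR-99a and let-7b were 2.43-fold, 2.42-fold and 2.33-fold lower, calls that ended with slide as a block (log2 -0.61, -0.63 and -0.57 against -1.28, -1.27 and -1.22 without it; adjusted p = 0.106, 0.0945 and 0.198). Of the leukocyte-enriched list, 4 of 8 tested members rose and 0 fell, and also 4 when adjusted over the list alone, but with slide as a block only 2. The list as a whole missed the threshold (mean log2 1.45, 1.11 with slide as a block, adjusted p = 0.0521). Over all 9 listed miRNAs with a probe, tested or not, its mean signal was -1.31 on day 28 replicate 2. On the other day 28 arrays it was -2.17 to -1.94, so the block shift of the list may rest on replicate 2 too. Of the injury-associated list, 4 of 7 members rose, among them miR-146b, an inducible miRNA of inflammatory signalling (log2 2.06 ± 0.18 SE), and 2 fell, among them miR-214 (log2 -1.33 ± 0.19 SE). The counts were 4 and 2 adjusted over the list alone and 2 and 1 with slide as a block, and the list test gave adjusted p = 0.536. The miR-17-92 cluster and its paralogs, known for a role in cell proliferation, rose as a list (mean log2 0.73, 0.64 with slide as a block, adjusted p = 0.0284). Of its 9 tested members 5 rose, also 5 adjusted over the list alone and 3 with slide as a block, with miR-19a at log2 1.80 ± 0.22 SE and miR-19b at log2 1.16 ± 0.14 SE. This call was lost with adjusted p = 0.745 with an estimated correlation, without day 1 replicate 3 (adjusted p = 0.0837) or uninjured replicate 3 (adjusted p = 0.103), and with median scaling (mean log2 0.08, adjusted p = 0.238). The let-7 family, known to restrain proliferation, fell as a list (mean log2 -0.47, adjusted p = 0.0279), with 5 of 9 members lower and 1 higher, also 5 and 1 adjusted over the list alone. Its shift was -0.10 with slide as a block (adjusted p = 0.286), where the calls of its members ended, and the list call was lost with adjusted p = 0.745 with an estimated correlation. The miR-199 and miR-214 list, miRNAs of mesenchymal cells, fell (mean log2 -0.86, -0.88 with slide as a block, adjusted p = 0.0279, but adjusted p = 0.745 with an estimated correlation). Of its 3 members 2 were lower, 3 adjusted over the list alone and 1 with slide as a block. The miR-181 family fell (mean log2 -0.56, -0.84 with slide as a block, adjusted p = 0.0418, but adjusted p = 0.745 with an estimated correlation). Of its 4 members 3 were lower, also 3 adjusted over the list alone, but these 3 calls ended with slide as a block. Leaving out day 1 replicate 3 or any 1 of the 3 uninjured arrays ended the miR-181 call (adjusted p = 0.0507 to 0.0823). limma called 104 of 321 miRNAs, 63 higher and 41 lower, and 30 with slide as a block (24 and 6), of which 29 were among the 104. All 104 kept their direction with the block. Without uninjured replicate 2 the count was 69. The direction of the balance rested on the scaling: the median log2 difference of all tested miRNAs was 0.24, and it was -0.34 with median scaling (17 higher, 103 lower), -0.31 with the 75th percentile over all probes (17 and 95) and -0.12 with quantile normalization (24 and 70). Without scaling the split was 34 higher and 2 lower, and with normexp background 18 and 29. The 75th percentile over all probes ended the miR-17-92, miR-199 and miR-214 and miR-181 list calls, quantile normalization those of let-7 and miR-199 and miR-214, median scaling and no scaling those of miR-17-92 and miR-181, and normexp background that of miR-181.

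Day 7 against uninjured covers the first week of the wall's response. miR-223 was 9.03-fold higher (log2 3.18 ± 0.17 SE, n = 3 and 3, adjusted p = 1.85e-08), and miR-155, made in activated immune cells, was 7.82-fold higher (log2 2.97 ± 0.31 SE, adjusted p = 5.57e-06). miR-21 and miR-146a rose 7.90-fold and 5.45-fold and miR-146b at least 8.15-fold, and miR-503, a relative of miR-16, rose at least 6.34-fold (log2 3.02 ± 0.16 SE). miR-143 and miR-145, transcribed together and typical of contractile smooth muscle, fell by 1.67 ± 0.23 (SE) and 1.92 ± 0.27 (SE) on the log2 scale. The largest decreases were in miR-129-5p, at least 11.8-fold lower (log2 -3.56 ± 0.54 SE), and in the neuronal miRNAs miR-124, 10.3-fold lower (log2 -3.37 ± 0.75 SE, adjusted p = 0.00209), and miR-137, 10.1-fold lower (log2 -3.33 ± 0.82 SE, adjusted p = 0.00388). miR-375 was at least 8.64-fold lower, at the floor on all 3 arrays of day 7, and miR-193b was 5.06-fold lower (log2 -2.34 ± 0.26 SE). With slide as a block, differences of these miRNAs ranged from -4.78 for miR-375, which rests largely on day 28 replicate 2, to 3.35 for miR-503, all still past the threshold. The injury-associated list rose (mean log2 1.79, 1.66 with slide as a block, adjusted p = 0.00225, but adjusted p = 0.413 with an estimated correlation). Of its 7 members 6 were higher, also 6 adjusted over the list alone. The leukocyte-enriched list rose (mean log2 1.68, 1.35 with slide as a block, adjusted p = 0.0122, but adjusted p = 0.413 with an estimated correlation). Of its 8 members 6 were higher, also 6 adjusted over the list alone. All 3 members of the miR-199 and miR-214 list, with negative differences at day 1, were higher at day 7 (3 adjusted over the list alone), with miR-214 at log2 1.17 ± 0.19 SE. That list had a mean log2 of 1.14 (1.12 with slide as a block) and adjusted p = 0.0394, but adjusted p = 0.413 with an estimated correlation and adjusted p = 0.0542 without uninjured replicate 3. The Dlk1-Dio3 cluster, an imprinted locus with many miRNA genes, rose (mean log2 0.57, adjusted p = 0.0274, but adjusted p = 0.65 with an estimated correlation). Of its 37 tested members 18 rose and 2 fell, and 19 and 2 adjusted over the list alone, with miR-299 at log2 1.69 ± 0.19 SE and miR-377 at log2 2.17 ± 0.25 SE. Its shift was 0.34 with slide as a block (adjusted p = 0.215). The call also ended without uninjured replicate 1 (mean log2 0.39, adjusted p = 0.116) or replicate 2 (adjusted p = 0.0518). miR-665, among the 18, and miR-134, not called, lay at the floor on all arrays outside day 7. They entered the test only through their day 7 signal, so they cannot count as support for the rise. The miR-30 family fell (mean log2 -0.96, -0.88 with slide as a block, adjusted p = 0.0122, but adjusted p = 0.413 with an estimated correlation). Of its 5 members 4 were lower, also 4 adjusted over the list alone. All 5 members of the miR-23/27/24 clusters fell (5 adjusted over the list alone; mean log2 -0.73, -0.68 with slide as a block, adjusted p = 0.023, but adjusted p = 0.413 with an estimated correlation). Without scaling, where the median of all tested miRNAs was 0.86, these 2 list means were 0.0080 and 0.24. In the smooth muscle list 2 of 6 members fell, also 2 adjusted over the list alone (list test adjusted p = 0.114). In the miR-34 family, known targets of p53, 3 of 4 members rose, also 3 adjusted over the list alone, with miR-34a at log2 2.17 ± 0.20 SE (list test adjusted p = 0.0755, and 0.0381 with slide as a block). The miR-15/16 family had 4 higher and 2 lower of 7 members (5 and 2 adjusted over the list alone), with a list test of adjusted p = 0.203, or 0.0381 with slide as a block. With an estimated correlation, tried only without the block, the miR-34 and miR-15/16 list tests gave adjusted p = 0.413 and 0.604. Higher members with slide as a block were 6 of the Dlk1-Dio3, 5 of the injury-associated and 4 of the leukocyte-enriched list. In that fit 3 members of the miR-30 family and 1 of the miR-23/27/24 clusters were lower. The miR-17-92 list had 4 of 9 members higher, also 4 adjusted over the list alone (adjusted p = 0.0509), and the miR-29 family 2 of 3 lower, also 2 adjusted over the list alone (adjusted p = 0.0882). limma called 160 miRNAs, 88 higher and 72 lower, and 92 with slide as a block (53 and 39), of which 89 were among the 160, and all 160 kept their direction. Without scaling the split was 122 and 9, and the list calls of Dlk1-Dio3, miR-199 and miR-214, miR-30 and miR-23/27/24 ended. The 75th percentile over all probes and median scaling also ended the miR-199 and miR-214 call (adjusted p = 0.0724 and 0.0512).

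**Figure D1:**
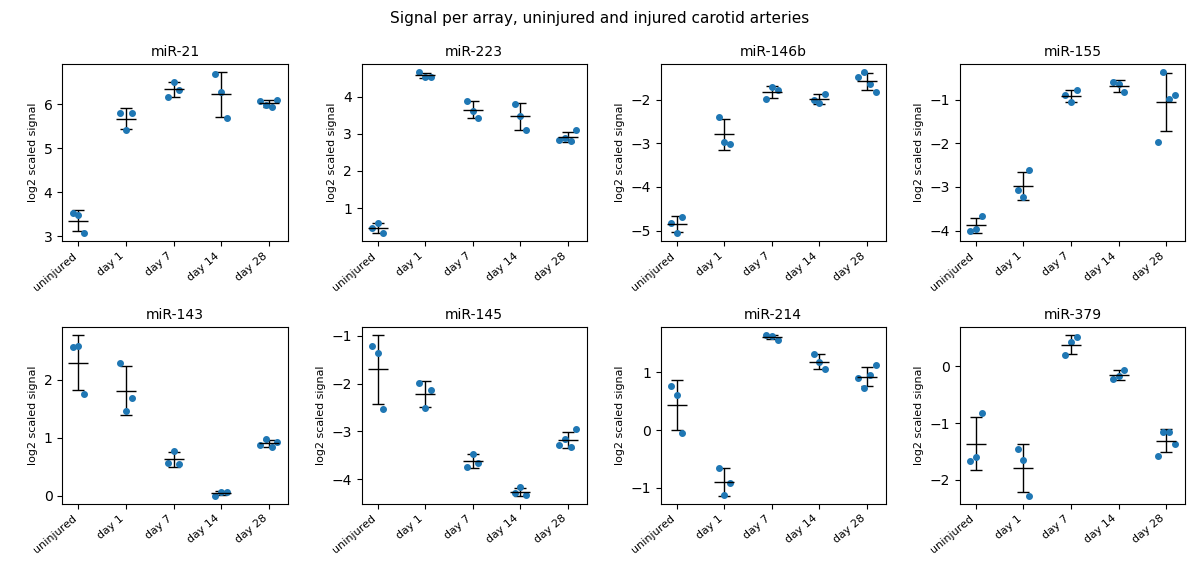
Log2 scaled signal (y axis) of 8 miRNAs on each array, by group (x axis: uninjured and injured day 1, day 7, day 14 and day 28); points are arrays, and the bar and whiskers give mean ± SD (n = 3, 3, 3, 3 and 4). miR-223 stood at 4.57 at day 1 and 2.91 at day 28, and miR-145 at -1.70 uninjured and -4.25 at day 14.

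Day 14 against uninjured lies within slide 2, so that slide cannot enter it. miR-155 was 9.17-fold higher (log2 3.20 ± 0.31 SE, n = 3 and 3, adjusted p = 3.83e-06), miR-223 8.01-fold (log2 3.00 ± 0.17 SE), miR-146b at least 7.32-fold and miR-21 7.30-fold (log2 2.87 ± 0.22 SE). miR-34a rose 6.89-fold (log2 2.78 ± 0.20 SE, adjusted p = 2.95e-07) and miR-503 at least 4.19-fold. miR-145 fell 5.86-fold (log2 -2.55 ± 0.27 SE, adjusted p = 1.06e-05) and miR-143 4.78-fold (log2 -2.26 ± 0.23 SE, adjusted p = 5.84e-06). miR-375 was at least 5.68-fold lower, and miR-193b and miR-378 were 3.98-fold and 3.84-fold lower. The smooth muscle contractile-associated list fell as a whole (mean log2 -1.15, adjusted p = 0.0119, but adjusted p = 0.28 with an estimated correlation). Of its 6 members 4 were lower, also 4 adjusted over the list alone. The leukocyte-enriched list rose (mean log2 1.68, adjusted p = 0.00115, but adjusted p = 0.28 with an estimated correlation). Of its 8 members 6 were higher, also 6 adjusted over the list alone. The injury-associated list rose (mean log2 1.59, adjusted p = 0.00115, but adjusted p = 0.28 with an estimated correlation). Of its 7 members 5 were higher, also 5 adjusted over the list alone. All 5 members of the miR-30 family fell, also 5 adjusted over the list alone (mean log2 -0.82, adjusted p = 0.00446, but adjusted p = 0.28 with an estimated correlation), with miR-30c at log2 -1.22 ± 0.14 SE. The miR-34 family rose (mean log2 1.40, adjusted p = 0.0292, but adjusted p = 0.28 with an estimated correlation). Of its 4 members 3 were higher, also 3 adjusted over the list alone. The miR-15/16 family rose (mean log2 0.79, adjusted p = 0.0266, but adjusted p = 0.329 with an estimated correlation). Of its 7 members 4 were higher, also 4 adjusted over the list alone, and the call ended without uninjured replicate 3 (adjusted p = 0.0811). The miR-23/27/24 clusters fell (mean log2 -0.51; 0.15 without scaling, where the median of all tested miRNAs was 0.52; adjusted p = 0.0311, but adjusted p = 0.418 with an estimated correlation). Of its 5 members 4 were lower, and 5 adjusted over the list alone. That call ended without day 14 replicate 1 (adjusted p = 0.0596) or uninjured replicate 1 (adjusted p = 0.0687). The miR-29 family, known to repress collagen genes, passed barely (mean log2 -0.70, adjusted p = 0.0499, but adjusted p = 0.28 with an estimated correlation). Of its 3 members 2 were lower, also 2 adjusted over the list alone. Its call ended when any 1 of 13 arrays was left out (highest adjusted p = 0.0698, without uninjured replicate 1); only without day 7 replicate 2, day 28 replicate 4 or uninjured replicate 3 was it kept. In the Dlk1-Dio3 list 8 of 37 members rose and 0 fell, with 6 adjusted over the list alone (list test adjusted p = 0.357). Of the miR-199 and miR-214 list, 2 of 3 members rose and 3 adjusted over the list alone (adjusted p = 0.0666), and of the miR-17-92 list 4 of 9, also 4 adjusted over the list alone (adjusted p = 0.0864). Day 14 replicate 1 stood apart: the neuronal miRNAs miR-124 and miR-137 lay at the floor there (log2 -5.79) and between -2.42 and -1.97 on the other day 14 arrays. limma called 126 miRNAs, 65 higher and 61 lower. With slide as a block the count was 129 (69 and 60), and with the arrays of slide 2 alone 126 (76 and 50), of which 106 were among the calls from all arrays. Median scaling moved the split to 52 higher and 76 lower, normexp background to 38 and 59, and no scaling to 68 and 4. The 75th percentile over all probes and median scaling each ended the miR-15/16, miR-23/27/24 and miR-29 calls, normexp background the last 2 of these, quantile normalization that of miR-29, and no scaling those of miR-23/27/24, miR-29 and miR-30.

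Day 28 against uninjured asks what remained 4 weeks after injury. miR-146b was at least 9.67-fold higher (log2 3.27 ± 0.17 SE, n = 4 and 3, adjusted p = 1.71e-08), miR-155 7.09-fold (log2 2.83 ± 0.29 SE), miR-21 6.35-fold (log2 2.67 ± 0.20 SE), miR-146a 6.12-fold, miR-223 5.44-fold (log2 2.44 ± 0.16 SE) and miR-34a 5.05-fold. miR-143 and miR-145 were 2.63-fold (log2 -1.39 ± 0.21 SE, adjusted p = 0.000317) and 2.77-fold lower (log2 -1.47 ± 0.26 SE, adjusted p = 0.00102), and miR-193b was 2.91-fold lower. Within slide 2 the difference of miR-145 was -1.43 (adjusted p = 0.0586) and that of miR-143 was -1.41 (adjusted p = 0.0134). miR-133a, a miRNA of skeletal and heart muscle, was 3.28-fold lower (log2 -1.72 ± 0.42 SE, adjusted p = 0.00862), with -1.34 and adjusted p = 0.0752 with slide as a block but adjusted p = 0.00603 within slide 2. The injury-associated list rose (mean log2 1.70, 1.63 with slide as a block and within slide 2, adjusted p = 4.99e-05, but adjusted p = 0.188 with an estimated correlation). Of its 7 members 5 were higher, and 6 adjusted over the list alone. The leukocyte-enriched list rose (mean log2 1.67, 1.5 with slide as a block and within slide 2, adjusted p = 9.54e-05, but adjusted p = 0.19 with an estimated correlation). Of its 8 members 6 were higher, also 6 adjusted over the list alone. The miR-15/16 family rose (mean log2 0.63, 0.80 with slide as a block and within slide 2, adjusted p = 0.0107, but adjusted p = 0.509 with an estimated correlation). Of its 7 members 4 were higher, and 6 adjusted over the list alone. The Dlk1-Dio3 list fell against the other miRNAs (mean log2 -0.31, -0.42 with slide as a block and within slide 2; 0.27 without scaling, where the median of all tested miRNAs was 0.63; adjusted p = 0.00251, but adjusted p = 0.682 with an estimated correlation). Only 3 of its 37 members were called, 1 higher and 2 lower, and 0 adjusted over the list alone by limma, and without uninjured replicate 3 its mean log2 was -0.02 (adjusted p = 0.22). The miR-17-92 list passed (mean log2 0.48, adjusted p = 0.0432, but adjusted p = 0.622 with an estimated correlation). Of its 9 members 3 were higher, also 3 adjusted over the list alone. It did not pass with slide as a block (0.44, adjusted p = 0.0722), without day 28 replicate 2 (adjusted p = 0.0841) or without uninjured replicate 3 (adjusted p = 0.205). The striated muscle list fell (mean log2 -1.06, adjusted p = 0.0435, but adjusted p = 0.533 with an estimated correlation). Of its 4 members 3 were lower, also 3 adjusted over the list alone. Its mean was -0.66 with slide as a block and within slide 2 (adjusted p = 0.124 with the block). The call ended without day 28 replicate 2 (mean log2 -0.83, adjusted p = 0.0965) or replicate 4 (adjusted p = 0.051), day 14 replicate 1 (adjusted p = 0.055), or uninjured replicate 1 (adjusted p = 0.0618) or replicate 3 (adjusted p = 0.0888). In the smooth muscle list 2 of 6 members fell, also 2 adjusted over the list alone (adjusted p = 0.0725), and in the miR-34 family 3 of 4 rose, also 3 adjusted over the list alone (adjusted p = 0.0815). Higher members with slide as a block were 4 of the injury-associated, 6 of the leukocyte-enriched, 6 of the miR-15/16 and 1 of the miR-17-92 list, and the member calls of the Dlk1-Dio3 and striated muscle lists ended. limma called 84 miRNAs, 54 higher and 30 lower, 55 with slide as a block (43 and 12) and 55 within slide 2 (44 and 11), of which 49 and 43 were among the 84. All 84 kept their direction in both. This is 1 check, as by design the differences with the block are those within slide 2. The split was 38 and 36 with quantile normalization, 30 and 41 with median scaling, 31 and 46 with normexp background, and 60 and 1 without scaling. Quantile normalization ended the list calls of miR-17-92 and striated muscle, and the 75th percentile over all probes and median scaling those and that of miR-15/16; normexp background ended the striated muscle call and no scaling the miR-17-92 call.

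**Figure D2:**
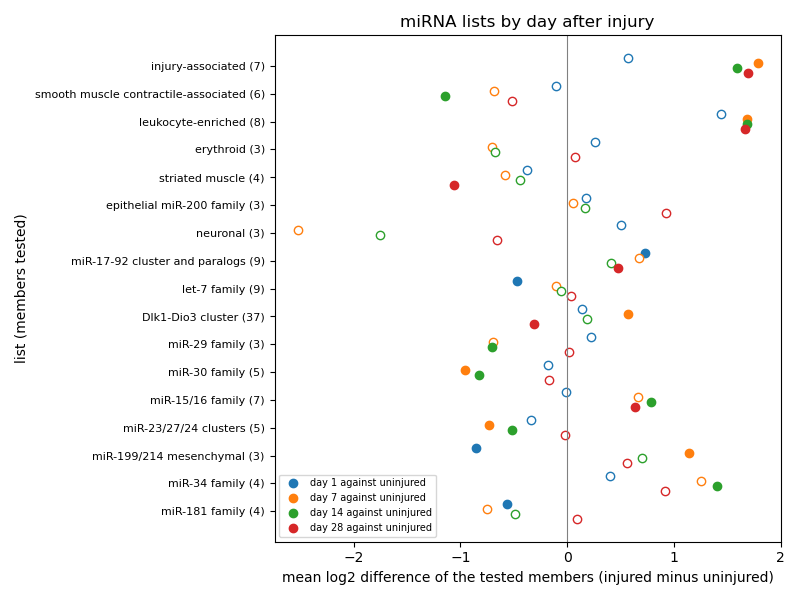
Mean log2 difference from uninjured of the tested members of each miRNA list (x axis) by list (y axis, members tested in brackets) and day (colours); filled points have a camera adjusted p under 0.05 with the preset correlation, and with an estimated correlation 0 lists do. The injury-associated list moved from 0.57 at day 1 (-0.0019 with median scaling) to 1.79 at day 7 and 1.70 at day 28, and the smooth muscle list reached -1.15 at day 14.

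Day 7 against day 1 lies within slide 1 and tests whether the effect of injury differed between the days. miR-299 and miR-379 of the Dlk1-Dio3 cluster rose at least 6.99-fold (log2 2.88 ± 0.19 SE, n = 3 and 3, adjusted p = 4.53e-07) and 4.52-fold (log2 2.18 ± 0.24 SE). miR-214, of a locus active in mesenchymal cells, rose 5.69-fold (log2 2.51 ± 0.19 SE, adjusted p = 5.51e-07), and miR-34a 5.26-fold (log2 2.39 ± 0.20 SE). miR-155 rose by 2.06 ± 0.31 (SE) on the log2 scale, while miR-223 fell by 0.93 ± 0.17 (SE). The neuronal miRNAs miR-137 and miR-124 fell 21.9-fold (log2 -4.45 ± 0.82 SE, adjusted p = 0.000767) and 14.9-fold (log2 -3.89 ± 0.75 SE, adjusted p = 0.00105). miR-7b, miR-138 and miR-153 fell at least 15.1-fold, 10.9-fold and 8.97-fold. The miR-199 and miR-214 list rose, with 3 of 3 members higher, also 3 adjusted over the list alone (mean log2 2.00, adjusted p = 0.00104, but adjusted p = 0.214 with an estimated correlation). The injury-associated list rose, with 6 of 7 members higher and 7 adjusted over the list alone (mean log2 1.21, adjusted p = 0.00104, but adjusted p = 0.214 with an estimated correlation). The Dlk1-Dio3 list rose, with 11 members higher and 2 lower of 37, also 11 and 2 adjusted over the list alone (mean log2 0.44, adjusted p = 0.00382, but adjusted p = 0.741 with an estimated correlation). Without day 1 replicate 3 that mean was 0.18 (adjusted p = 0.0628). Among the 11 is miR-665, which lay at the floor on all arrays outside day 7 and was tested only through its day 7 signal. The miR-15/16 family rose through miR-503 (log2 2.09 ± 0.16 SE) and miR-322 (log2 1.44 ± 0.24 SE), 2 of its 7 members and also 2 adjusted over the list alone (mean log2 0.68, adjusted p = 0.025, but adjusted p = 0.465 with an estimated correlation, 0.0628 without day 1 replicate 1 and 0.111 with quantile normalization). All 5 members of the miR-30 family fell, also 5 adjusted over the list alone (mean log2 -0.77, adjusted p = 0.025, but adjusted p = 0.465 with an estimated correlation, and adjusted p = 0.0506 without day 7 replicate 1). All 3 members of the miR-29 family fell, also 3 adjusted over the list alone (mean log2 -0.93, adjusted p = 0.0485, but adjusted p = 0.401 with an estimated correlation). The miR-29 call ended without day 1 replicate 1 or 3, day 7 replicate 1, day 14 replicate 3 or uninjured replicate 2 (adjusted p = 0.0525 to 0.0628). The let-7 list rose with 1 of 9 members past the threshold, let-7i (log2 0.94 ± 0.19 SE), also 1 adjusted over the list alone (mean log2 0.37, adjusted p = 0.0485, but adjusted p = 0.741 with an estimated correlation). The let-7 call ended without day 1 replicate 1 or 3, day 7 replicate 1 or 3, day 14 replicate 3 or any 1 uninjured array (adjusted p = 0.0527 to 0.0978). The smooth muscle list had 3 of 6 members lower and 1 higher, also 3 and 1 adjusted over the list alone, with miR-143 at log2 -1.19 ± 0.23 SE (list test adjusted p = 0.387). The leukocyte-enriched list had 3 of 8 higher and 1 lower, also 3 and 1 adjusted over the list alone, and its mean (0.24) and median (-0.28) differed in sign (adjusted p = 0.49). The miR-34 family had 3 of 4 higher and 1 lower, also 3 and 1 adjusted over the list alone (adjusted p = 0.0621). limma called 139 miRNAs, 60 higher and 79 lower. The split was 64 and 77 with slide as a block and 60 and 93 within slide 1. List shifts were the same in all 3 fits, as they must be for 2 groups that lie wholly on 1 slide. The median log2 difference of all tested miRNAs was -0.19, and it was 0.27 with the 75th percentile over all probes (99 higher, 32 lower), 0.27 with median scaling (103 and 36), 0.07 with quantile normalization (88 and 51) and 0.50 without scaling (67 and 11). The first 2 of these scalings and no scaling ended the miR-29 and miR-30 list calls, and quantile normalization and no scaling that of let-7.

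Day 14 against day 7 lies between the slides. miR-24-1*, miR-331-3p and miR-224, none of them in a list, differed by log2 0.89 ± 0.16 (SE, n = 3 and 3, adjusted p = 0.0102), 0.79 ± 0.15 (SE) and -0.97 ± 0.19 (SE). miR-377 and miR-541 of the Dlk1-Dio3 cluster were 2.20-fold and at least 2.10-fold lower, and miR-19a of the miR-17-92 cluster 2.07-fold lower. All of these calls ended with slide as a block, where the first 3 differed by 0.51, 0.74 and -1.13 (adjusted p = 0.443, 0.339 and 0.204). Without day 14 replicate 2 the first 3 and miR-541 stood at adjusted p = 0.0531 each and miR-377 and miR-19a at 0.087 and 0.0811; without day 7 replicate 2 miR-541 stood at 0.0621 and the last 2 at 0.067 each. The Dlk1-Dio3 list fell (mean log2 -0.39, adjusted p = 0.00258, but adjusted p = 0.973 with an estimated correlation). Of its 37 members 2 were lower, also 2 adjusted over the list alone. That shift was -0.16 with slide as a block (adjusted p = 0.277) and -0.27 without day 14 replicate 1 (adjusted p = 0.127). In the other lists with at least 3 tested members the tests gave adjusted p = 0.0919 or higher. In the fit with slide as a block the smooth muscle list fell (mean log2 -0.46) and the epithelial, neuronal and miR-181 lists rose (1.89, 1.59 and 0.54; adjusted p = 0.0442 each). Without the block these 4 shifts were -0.46, 0.11, 0.78 and 0.26. With an estimated correlation, tried only without the block, adjusted p was 0.973 for each. The block rests on the day 28 arrays. On replicate 2 of these the epithelial list stood at -1.59 against -5.68 to -5.38 on the others (5 miRNAs with a probe, 3 tested). The miR-181 list stood there at -1.76 against -2.76 to -2.54. The epithelial rise with the block thus rests largely on that array, and the miR-181 rise may do so as well. Among the called members were miR-365 of the smooth muscle list (1 of 6 lower, also 1 adjusted over the list alone), miR-342-3p of the leukocyte list (1 of 8 higher, also 1 adjusted over the list alone) and miR-497 and miR-195 of the miR-15/16 family (2 higher and 1 lower of 7, also 2 and 1 adjusted over the list alone). Without day 14 replicate 2 these 4 stood at adjusted p = 0.139, 0.0705, 0.087 and 0.087, and all 4 calls also ended without day 7 replicate 2 (0.067 for miR-497). The let-7 family had 2 of 9 members lower, and 1 higher and 2 lower adjusted over the list alone. Its mean log2 was 0.04 (adjusted p = 0.893, and 0.973 with an estimated correlation) but -0.33 with slide as a block (adjusted p = 0.0442). The block shift may rest on day 28 replicate 1, where the list stood at 3.16 against 3.78 to 3.84 on the other day 28 arrays. limma called 33 miRNAs, 13 higher and 20 lower, and 0 with slide as a block, with 29 at an unadjusted p under 0.05. Without day 14 replicate 2 the count was 1, without day 7 replicate 2 it was 5, without day 7 replicate 3 it was 18, and without uninjured replicate 2 it was 21. With median scaling the split was 5 higher and 17 lower, with the 75th percentile over all probes 0 and 2, and without scaling limma called 0, with 31 at an unadjusted p under 0.05. These differences cannot be told apart from a difference between the slides.

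Day 28 against day 14 shows what changed late. miR-30c and miR-29b rose 1.95-fold each (log2 0.97 ± 0.13 SE and 0.97 ± 0.17 SE, n = 4 and 3, adjusted p = 0.00118 and 0.00295), and miR-29c rose by log2 0.86 ± 0.13 (SE). miR-431, miR-379 and miR-299 of the Dlk1-Dio3 cluster fell 2.57-fold (log2 -1.36 ± 0.26 SE, adjusted p = 0.00467), 2.23-fold and 2.07-fold, and miR-503 fell 2.02-fold. With slide as a block these 7 miRNAs kept their calls (adjusted p = 0.0111 to 0.03), but within slide 2, with 2 arrays of day 28, adjusted p was 0.0667 or higher for each of them. Their differences in both fits were 0.94, 0.78, 0.87, -1.31, -1.10, -0.85 and -0.85. The Dlk1-Dio3 list fell, with 7 of 37 members lower, also 7 adjusted over the list alone (mean log2 -0.49, -0.61 with slide as a block and within slide 2, adjusted p = 4.79e-09, but adjusted p = 0.462 with an estimated correlation). The miR-30 family rose, with 3 of 5 members higher and 5 adjusted over the list alone (mean log2 0.65, 0.69 with slide as a block and within slide 2, adjusted p = 0.00117, but adjusted p = 0.425 with an estimated correlation). The miR-29 family rose, with 2 of 3 members higher and 3 adjusted over the list alone (mean log2 0.72, 0.73 with slide as a block and within slide 2, adjusted p = 0.00816, but adjusted p = 0.36 with an estimated correlation). The smooth muscle list rose (mean log2 0.63, 0.64 with slide as a block and within slide 2, adjusted p = 0.0111, but adjusted p = 0.425 with an estimated correlation). Of its 6 members 4 were higher, also 4 adjusted over the list alone. These were miR-365, miR-125b-5p, miR-145 (log2 1.08 ± 0.26 SE) and miR-143 (log2 0.86 ± 0.21 SE), which without day 14 replicate 1 stood at adjusted p = 0.0524, 0.0569, 0.0524 and 0.0604. With slide as a block miR-125b-5p and miR-143 differed by 0.70 and 0.84 (adjusted p = 0.07 each). The miR-23/27/24 clusters rose, with 3 of 5 members higher, also 3 adjusted over the list alone (mean log2 0.49, 0.52 with slide as a block and within slide 2, adjusted p = 0.0111, but adjusted p = 0.464 with an estimated correlation). The miR-34 family fell, with 2 of 4 members lower and 3 adjusted over the list alone (mean log2 -0.49, -0.37 with slide as a block and within slide 2, adjusted p = 0.0369, but adjusted p = 0.462 with an estimated correlation). Its call ended with slide as a block (adjusted p = 0.0965) and without day 28 replicate 1 (adjusted p = 0.0726) or day 14 replicate 1 (mean log2 -0.29, adjusted p = 0.12). The miR-181 family rose, with 1 of 4 members higher, also 1 adjusted over the list alone (mean log2 0.58, 0.44 with slide as a block and within slide 2, adjusted p = 0.0426, but adjusted p = 0.468 with an estimated correlation). This call ended with slide as a block (adjusted p = 0.153) and without day 1 replicate 1, day 28 replicate 2, day 14 replicate 1 or 2, or uninjured replicate 1 or 3 (adjusted p = 0.0533 to 0.0986; mean log2 0.36 without day 28 replicate 2). Under the slide block 5 members of the Dlk1-Dio3 list were lower, and 3 of the miR-30, 3 of the miR-29, 2 of the smooth muscle and 1 of the miR-23/27/24 list were higher. limma called 49 miRNAs, 31 higher and 18 lower, 28 with slide as a block (20 and 8, of which 25 were among the 49) and 0 within slide 2, with 81 at an unadjusted p under 0.05. All 49 kept their direction in both, which is 1 check, as by design the differences with the block are those within slide 2. Without day 14 replicate 1 the count was 21, and without day 14 replicate 2 it was 30. With day 14 replicate 1 and day 28 replicate 2 both left out, an alternative chosen after the data had been seen, it was 13. The split was 13 and 12 with the 75th percentile over all probes, 14 and 17 with median scaling and 17 and 21 with quantile normalization, and without scaling limma called 0, with 19 at an unadjusted p under 0.05. Quantile normalization ended the miR-23/27/24 call, median scaling that of miR-181, and no scaling these and the miR-34 call.

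Over all 4 days the moderated F test of limma called 196 of 321 miRNAs, and 166 with slide as a block. In the fit without a block, at every day 23 miRNAs were called higher, among them miR-21, miR-21*, miR-146a, miR-146b, miR-155, miR-223, miR-142-3p, miR-142-5p, miR-340-5p, miR-362-5p and miR-503. Another 8 were called lower at every day, among them miR-375, miR-193b, miR-100 and miR-30a. Of these, with slide as a block, 14 of the 23 and 1 of the 8, miR-375, passed at every day. The block values of miR-375 at day 1 and day 7 rest largely on day 28 replicate 2. It stood at -3.20 there and at -5.79 to -5.03 on the other day 28 arrays. miR-155, miR-146a, miR-142-5p, miR-193b, miR-100 and miR-30a did not pass at day 1 with the block (adjusted p = 0.213, 0.246, 0.0513, 0.306, 0.106 and 0.341). Their day 1 differences were 1.15, 0.60, 1.63, -0.66, -0.61 and -0.39 with the block, against 0.90, 0.60, 2.68, -1.26, -1.28 and -0.83 without it. If the calls of the 4 days were independent, 0.588 and 0.163 would be shared, and in 100 simulations of unchanged groups with the same control arrays the means were 0 and 0.01, which does not address slide. With no miRNA changed few calls arise at any day, so the simulations cannot show how far the shared control arrays raise the overlap. Day 7 and day 14 shared 53 higher and 55 lower calls, against 17.8 and 13.7 if they were independent. In the simulations, with the same limit, the means were 0 and 0.02. With the slide block day 7 and day 14 shared 43 and 35, against 11.4 and 7.29 if independent. The 4 comparisons use the same 3 uninjured arrays, so that their calls are not independent of each other.

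The remaining lists hold markers of other cells and tissues. miR-126-3p, the endothelial miRNA tested, was higher at day 7 than uninjured (log2 0.45 ± 0.16 SE, n = 3 and 3, adjusted p = 0.0305), a call lost without day 7 replicate 2 or 3 or uninjured replicate 1 or 2 (adjusted p = 0.061 to 0.109), and higher than at day 1 (log2 0.65 ± 0.16 SE, adjusted p = 0.005). At day 1, day 14 and day 28 it differed from uninjured by log2 -0.20, 0.37 and 0.42 (adjusted p = 0.353, 0.084 and 0.0572). Its differences with slide as a block were 0.17 at day 1 (adjusted p = 0.738), 0.82 at day 7 (adjusted p = 0.0149) and 0.60 at day 28 (adjusted p = 0.0189). miR-210, the hypoxia-associated miRNA, was lower at day 7 (log2 -0.85 ± 0.22 SE, adjusted p = 0.00636; 0.12 without scaling, where the median of all was 0.86) and differed by -0.35 with slide as a block (adjusted p = 0.488). At day 1 its difference was -0.84 ± 0.22 (SE, adjusted p = 0.013), a call lost without day 1 replicate 1 or 2 or uninjured replicate 2 (adjusted p = 0.0528 to 0.0603) and with slide as a block (-0.34, adjusted p = 0.58). Of the 3 erythroid miRNAs 0 were called by limma at any day, also 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05, miR-486 at day 7 (log2 -1.20 ± 0.48 SE, adjusted p = 0.0542). The striated muscle list had 1 of 4 members lower at day 7, miR-133a, and 2 at day 14, miR-1 (log2 -1.48 ± 0.36 SE) and miR-133a. Adjusted over the list alone 1 was lower at day 7, and 2 were lower and 1 higher at day 14. The list tests gave adjusted p = 0.338 and 0.278. The day 7 call of miR-133a ended with slide as a block (-0.94, adjusted p = 0.353). The day 14 call of miR-133a ended without day 14 replicate 1 or 2 or uninjured replicate 1 or 3 (adjusted p = 0.0527 to 0.0654). The neuronal list had 2 of 3 members lower at day 7, also 2 adjusted over the list alone (mean log2 -2.53, adjusted p = 0.0998). It passed with slide as a block (-3.34, adjusted p = 0.0381, 3 of 3 members lower), as did the miR-181 list at day 7 (-1.03, adjusted p = 0.0381, against -0.75 and 0.0882 without the block). With an estimated correlation, tried only without the block, these 2 lists had adjusted p = 0.413 and 0.467. The miR-181 block shift may rest on day 28 replicate 2, at -1.76 against -2.76 to -2.54 on the other day 28 arrays. At day 14 the neuronal list had 2 lower, miR-137 and miR-124 (adjusted p = 0.143), which within slide 2 alone had the same differences (-2.39 and -2.05) but adjusted p = 0.137 and 0.168. The day 14 calls of miR-137 and miR-124 stood at adjusted p = 0.105 and 0.155 without day 14 replicate 1, and at 0.112 and 0.142 without uninjured replicate 3; that of miR-124 was lost without any 1 of 12 arrays. The epithelial miR-200 family had 3 of 5 members tested and 0 called by limma at any day, also 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05. Over all 5 members, tested or not, its mean scaled log2 signal was -1.59 on day 28 replicate 2, against -5.68 to -5.38 on the other day 28 arrays. Through replicate 2 the slide block moved the day 1 shift of the 3 tested members from 0.17 to -1.61. Their day 7 shift moved from 0.06 to -1.73. The liver miRNA on the array was not tested, as its probe was well above background on all arrays of no group. Mean, median and list test did not all share a sign for lists that were not called: the epithelial list at day 1 and day 7, Dlk1-Dio3 and miR-15/16 at day 1, and the erythroid, let-7, miR-29, miR-23/27/24 and miR-181 lists at day 28. The same held between days for the leukocyte, epithelial and miR-17-92 lists from day 1 to day 7, the leukocyte, erythroid, epithelial and miR-29 lists from day 7 to day 14, and miR-15/16 from day 14 to day 28.

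**Figure D3:**
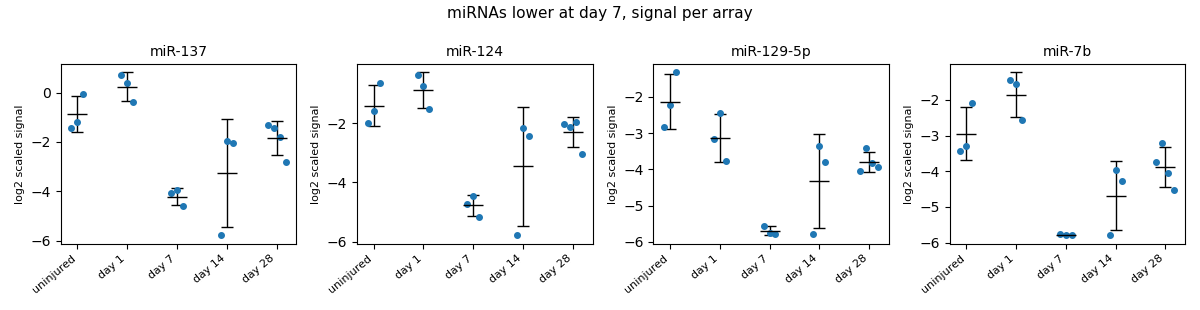
Log2 scaled signal (y axis) of miR-137, miR-124, miR-129-5p and miR-7b on each array, by group (x axis: uninjured and injured day 1, day 7, day 14 and day 28); points are arrays, and the bar and whiskers give mean ± SD (n = 3, 3, 3, 3 and 4). On day 14 replicate 1 all 4 lay at the floor of -5.79, and at day 7 miR-137 lay between -4.60 and -3.96.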

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

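The tests of the miRNAs lowest at day 7, of the balance of calls at day 1 and of the epithelial miRNAs on 1 array were chosen only after the result was seen; the comparisons of successive days and the other splits of the arrays were chosen before.

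Among the day 28 arrays 3 list means had 1 array far from the others, by the ratio of its gap to the whole range. These means take all listed miRNAs with a probe, tested or not: 5 (3 tested) for the epithelial list and 59 (37 tested) for Dlk1-Dio3. The epithelial miR-200 family stood at -1.59 on replicate 2 against -5.68 to -5.38 (ratio 0.926), the let-7 family at 3.16 on replicate 1 against 3.78 to 3.84 (ratio 0.911), and the Dlk1-Dio3 cluster at -4.48 on replicate 4 against -4.26 to -4.22 (ratio 0.848). Chance picks out about 1 in 20 groups in this way, so a few of the items screened would be picked out by chance alone.

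The effect of injury differed for 139 miRNAs from day 1 to day 7, within slide 1. From day 14 to day 28 it was 49, or 28 with slide as a block and by limma 0 within slide 2 (81 unadjusted). The 33 calls from day 7 to day 14 cannot be told apart from slide: with slide as a block limma called 0 (29 unadjusted). From day 1 to day 7 the named miRNAs differed by log2 2.88 (miR-299), 2.51 (miR-214), 2.39 (miR-34a), 2.21 (miR-299*), 2.18 (miR-379), -4.45 (miR-137), -3.92 (miR-7b), -3.89 (miR-124), -3.45 (miR-138) and -3.17 (miR-153). From day 7 to day 14, between slides, the values were 0.89 (miR-24-1*), 0.83 (miR-10b), 0.80 (miR-497), 0.79 (miR-331-3p), 0.77 (miR-1892), -1.14 (miR-377), -1.12 (miR-541), -1.05 (miR-19a), -0.97 (miR-224) and -0.86 (miR-365). All 10 calls were lost without day 14 replicate 2. From day 14 to day 28 they were 1.67 (miR-338-3p), 1.22 (miR-204), 1.08 (miR-145), 0.97 (miR-29b), 0.97 (miR-30c), -1.36 (miR-431), -1.16 (miR-379), -1.05 (miR-299), -1.02 (miR-337-5p) and -1.01 (miR-503). With slide as a block 3 of the 5 higher and 4 of the 5 lower calls remained, with differences of 0.78 to 1.51 and -1.31 to -0.85. Within slide 2, with the same differences, 0 of these calls remained. Without day 14 replicate 1, miR-338-3p, miR-204 and miR-145 stood at adjusted p = 0.07, 0.0741 and 0.0524, and without day 14 replicate 2 miR-337-5p stood at 0.0582.

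Other splits of the arrays into groups of the same sizes show how often chance alone gives as many calls. In the comparison of day 28 with uninjured 1 of 35 splits, the real one, gave as many calls (84 against at most 48 in the others). In that of day 28 with day 14 it was also 1 of 35 (49 against at most 27), and over all groups 1 of 100 drawn (196 against at most 11). These shares lie under 0.05, which makes chance unlikely there but does not exclude it. The splits were made without regard to slide, so a difference between slides is not excluded by them; with slide as a block the counts were 55, 28 and 166. The comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05. The real split and the highest other gave 104 and 34 calls at day 1, 160 and 0 at day 7, 126 and 0 at day 14, 139 and 0 between day 1 and day 7, and 33 and 8 between day 7 and day 14.

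Probes for 39 viral miRNAs were outside the comparisons. Those well above background on injured arrays but on 0 uninjured arrays, and with a higher mean on injured arrays, were mcmv-miR-m01-2 on 6 arrays, mghv-miR-M1-6 on 2, and mcmv-miR-m59-2, mcmv-miR-m88-1* and mghv-miR-M1-8 on 1 each. Other viral probes were detected on uninjured arrays too: mcmv-miR-M23-1-5p and mghv-miR-M1-2 on all 16 arrays, and mcmv-miR-m88-1 on 15, of which 2 were uninjured. Their mean log2 signals were -2.27, -3.14 and -4.85 on uninjured and -2.44, -3.13 and -5.12 on injured arrays. mcmv-miR-M87-1, on 2 injured and 0 uninjured arrays, had a lower mean on injured arrays (-5.76 against -5.72). Viral probe signal was thus not confined to injured arteries. No explanation was tested for these signals.

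The 10 miRNAs named as lower at day 7, among them miR-129-5p, miR-124 and miR-137, had a median difference from uninjured of log2 -2.76. The scalings tried did not remove this decrease, as the highest median over them was -2.06. They moved the median of all tested miRNAs at day 7 only to between -0.13 and 0.86, and the 10 were picked for their large decreases. This outcome was thus close to fixed in advance, and no conclusion beyond these scalings is drawn. Slide is argued against, as the median against day 1 within slide 1 was -2.91. With slide as a block, which rests on the day 28 arrays, the median from uninjured was -3.65. Unequal amounts of attached tissue in the samples may contribute: after group means were subtracted the 10 miRNAs varied together with a mean pairwise correlation of 0.509, above the 95th percentile of random sets (0.207), and 3 of 10000 such sets were as high. On day 14 replicate 1, 7 of the 10 lay at the floor; without that array the correlation was 0.470, against 0.243 for random sets. Of the 10, 2 are in the neuronal list, which has only 3 tested members and takes no star forms. For that reason miR-9*, 1 of the 10, was not counted although miR-9 is listed. The 2 are therefore not a count of all neuronal miRNAs in the set. A biological change in the artery at day 7, which the design names as a group, stays open and untested.

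At day 1 there were more higher than lower calls (63 and 41). This balance may come from array scaling, since over the scaling alternatives the share of higher calls went down to 14.2%. Array brightness stays open: within groups, the 75th percentile of the 16 arrays and the difference between dimmer and brighter miRNAs were related with r = -0.0319 (permutation p = 0.921, 1 relation computed; rank correlation 0.0588, permutation p = 0.853). Without the 2 arrays farthest from the median r was 0.175. No biological explanation was tested.

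On day 28 replicate 2 alone, miR-200a, miR-200b, miR-200c, miR-141, miR-429 and miR-205 stood at -1.78, -1.35, -1.26, -1.51, -2.07 and -1.54, each above all other arrays. Damage or dirt on only a few spots is argued against, as 100% of the 100 spots for the miR-200 family (all but miR-205) were well above background there. These miRNAs were picked for their high signal there, and bright dirt on all of these spots would give the same count. The count therefore cannot speak to that. Attached epithelial tissue stays open: of 4 other epithelial miRNAs, 1 was highest there (miR-203 at -4.79), while miR-182, miR-183 and miR-96 at -5.28, -3.32 and -2.74 were brighter on arrays without miR-200a (up to -3.31, -1.28 and -2.09). These 3 thus had another source on those arrays, which voids the bound set for them, although the count met it. No biological explanation was tested.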

How the results depend on the processing

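Leaving out both arrays that stand apart (day 14 replicate 1 and day 28 replicate 2) was the only test here chosen after the result was seen.

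Under alternatives other than leaving out an array, 9790 of 11199 values of named miRNAs were kept: called in the same direction in both fits, or in neither. Values called in neither fit count as kept even where their sign changed. Of the rest 1086 no longer passed, 298 newly passed and 25 reversed, a change of sign with a call in at least 1 of the 2 fits. For lists the numbers were 2539 of 2791, 157, 90 and 5. With arrays left out in turn, 7550 of 8016 miRNA values and 1821 of 1904 list values were kept, 369 and 58 no longer passed, 97 and 25 newly passed, and 0 reversed. The total count of calls, whatever their direction, stayed within 1.5 times the reported count in 31 of 38 alternatives at day 1. It did so in 35 of 38 at day 7, 37 of 39 at day 14 and 34 of 39 at day 28. For successive days, in order, the numbers were 37 of 39, 22 of 38 and 26 of 39, and over all groups 35 of 36. These alternatives include the fits with an array left out, which share most of their arrays. A count within this range can still reverse its balance. At day 1 the reported split was 63 higher and 41 lower. It was 17 and 103 with median scaling and 24 and 70 with quantile normalization, both within the range. From day 1 to day 7 these scalings gave 103 and 36 and 88 and 51, against 60 and 79 reported, also within it.

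With arrays left out in turn the counts ranged from 69 to 117 at day 1, 138 to 166 at day 7, 85 to 134 at day 14, 63 to 86 at day 28, 107 to 155 from day 1 to day 7, 1 to 49 from day 7 to day 14, 21 to 55 from day 14 to day 28, 183 to 213 over all groups and 21 to 25 for lists called against uninjured. The lowest came without uninjured replicate 2 at day 1 (69), day 14 replicate 2 from day 7 to day 14 (1) and day 14 replicate 1 from day 14 to day 28 (21).

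The calls from day 7 to day 14 and from day 14 to day 28 numbered 2 and 25 with scaling to the 75th percentile over all mouse probes, 7 and 28 with total gene signal, 5 and 26 with the authors' value table, and 16 and 31 with normexp background, which gave 47 at day 1. Median scaling gave 31 from day 14 to day 28. No scaling gave 36 at day 1, 72 at day 14, 78 from day 1 to day 7, 115 over all groups, and by limma 0 from day 7 to day 14 and 0 from day 14 to day 28 (31 and 19 at an unadjusted p under 0.05). The cause was not tested.

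Slide as a fixed block gave 30 at day 1, 92 at day 7, 55 at day 28, by limma 0 from day 7 to day 14 (29 unadjusted) and 28 from day 14 to day 28; slide as a random block gave 21 from day 7 to day 14. Within 1 slide, with fewer arrays, there were 55 calls at day 28 and by limma 0 from day 14 to day 28 (81 unadjusted). Only the 2 groups compared gave 44 at day 28 and 61 from day 7 to day 14. Array weights gave 198 at day 1 and 130 from day 7 to day 14, from an estimate that did not reach its convergence tolerance. A log2 difference of at least 1 as well, which by construction gives fewer calls, left 53, 96, 75 and 34 at the 4 days and 75, 3 and 8 between successive days. The estimated correlation left 0 lists called by camera. Both arrays that stand apart left out gave 13 from day 14 to day 28. Except where the construction shows it, the cause was not tested.

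Replicate numbers were tried as a block. It gave 92, 153, 116 and 66 calls at the 4 days and 137, 16 and 34 between successive days; with slide block as well it gave 10 at day 1, 45 at day 7, 21 at day 28, and by limma 0 from day 7 to day 14 and 0 from day 14 to day 28 (11 and 42 unadjusted). Deviations of arrays with the same number had a median correlation of -0.06 over 30 pairs, against 0.02 over 72 pairs with different numbers, and 4 of 16 arrays correlated best with their own number, so the numbers do not pair the animals.

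Reversed values were, at day 1, miR-30b -0.15 and miR-16 -0.15 with scaling to the 75th percentile over all mouse probes, and miR-29c -0.65 (adjusted p = 0.0223), miR-30b -0.17 and miR-16 -0.17 with median scaling. At day 7 let-7c was 0.053 with quantile normalization, and with no scaling miR-210 was 0.12, let-7b 0.13, let-7c 0.36, miR-29a 0.17, miR-30e 0.28, miR-195 0.18, miR-24 0.16, miR-27a 0.35, miR-27b 0.40, the miR-30 family list 0.0080 and the miR-23/27/24 clusters list 0.24. No scaling also reversed, at day 14, miR-29b 0.16, miR-27b 0.14, miR-27a 0.24, miR-24 0.27 and the miR-23/27/24 clusters list 0.15. At day 28 it reversed miR-29c 0.19, miR-30a 0.0040 and the Dlk1-Dio3 cluster list 0.27, and from day 1 to day 7 miR-29a 0.19, miR-30e 0.036 and miR-30b 0.058. Without scaling the median of all tested miRNAs was itself 0.86 at day 7, 0.52 at day 14, 0.63 at day 28 and 0.50 from day 1 to day 7, so the values given for no scaling still lie below it. At day 1 that median moved from 0.24 to -0.31 with the 75th percentile over all mouse probes and to -0.34 with median scaling. The reversed values of miR-30b and miR-16 lie above these medians, and that of miR-29c lies below. From day 7 to day 14 the let-7 family list was -0.33 with slide as a fixed block, and miR-29a was -0.018 in the replicate block with slide block. The cause was not tested.

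Signal over background limits the measured set: of the 611 mouse miRNAs only 321 were tested, and a fold from the floor of log2 -5.79 is a lower bound.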

Other observations

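The grouping of miRNAs by neighbouring genes given here was chosen only after the values were seen; the test of neighbouring genes was chosen before.

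The gene set of miR-322, miR-503, miR-542 and miR-450b-3p (5 miRNAs tested) had mean log2 differences from uninjured of 0.0068, 1.36, 1.12 and 0.44 at day 1, day 7, day 14 and day 28, with 1, 4, 4 and 1 members called higher. At day 1 it also had 1 member called lower. The set of miR-188-5p, miR-362, miR-500 and miR-532 (6 tested) had 0.89, 1.44, 1.26 and 1.11, with 3, 6, 6 and 5 called higher. Sets of miR-466, miR-467 and miR-669 miRNAs were highest at day 1, with 1.35, 0.29, 0.66 and 0.71 in a set of 10 (6, 1, 2 and 1 called higher) and 1.5, -0.024, 0.27 and 0.32 in a set of 9 (4, 0, 1 and 0 called higher). From day 1 to day 7, within slide 1, these sets differed by -1.07 and -1.52, with 3 members of the set of 9 called lower. With slide as a block the day 1 calls of the set of 10 all ended, as did those at day 7 and day 28, and 2 of 4 in the set of 9 remained, although the day 1 means were 1.38 and 2.00, no smaller than without the block. The miR-322 set then had 1, 5, 4 and 2 members higher and the miR-188-5p set 2, 6, 6 and 5. In the miR-322 set miR-450b-3p lay at the floor on all arrays outside day 7. It entered the test only through its day 7 signal, so it cannot count as support for the day 7 rise. miR-542-3p lay at the floor on all uninjured and day 1 arrays, so it too entered only through later days. The day 1 values lie on the scale on which the median of all tested miRNAs was 0.24.

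miRNA genes that lie close together may change together over the groups. This was tested on the 282 of 321 tested miRNAs with 1 gene in the RefSeq table. Over 362 pairs of neighbours within 10 kb the median correlation of the group means was 0.598, against a 95th percentile of 0.142 after shuffling, and 0 of 10000 shuffles were as high. Over the 100 pairs not both in the Dlk1-Dio3 list it was 0.681. The pairs share miRNAs and are not independent, and similar sequences within a cluster may also share signal between probes, which was not tested.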
